A study of Homo sapiens with 6 samples.

How the data were processed

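RNA-seq was analysed for 6 libraries of cisplatin-treated ME180 cells, 3 with an empty vector and 3 with a construct against VPS13C. Per the labels, reads were single-end, 50 bases long and made on a DNBSEQ instrument, and per the submitters' processing notes the genome build was hg38. The aligner, the counting tool and the strandedness are not given in the sources used here. The deposited gene table held 18358 genes with Entrez identifiers, and the deposited transcript table held 87783 RefSeq transcripts, 46329 with NM_ and 41454 with XM_ identifiers. Total counts per library ran from 14774065 to 15799149. Of the genes 693, and of the transcripts 11370, were at 0 in all libraries.

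The tables as deposited by the authors gave an expected count (estimated count of reads per gene or transcript, with fractions where reads were shared), which was rounded to whole numbers and used for all tests. FPKM values, scaled by the authors for length and library size, were used for an alternative and, with the counts, to derive gene lengths. TPM values as deposited by the authors were not used for any test. A further column of normalized signal, made by the authors as the rounded count times 1 factor per library, was used only for a check, and how the factor was found is not stated. Group mean columns by the authors were not used here. Coordinates came from a RefSeq table for GRCh38, in which 18200 Entrez identifiers were found.

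Genes were filtered with filterByExpr (minimum count 10), scaled with TMM factors and tested with edgeR 4.0.16 quasi-likelihood F-tests with robust dispersion in R 4.3.3, knockout against vector. Benjamini-Hochberg adjusted p under 0.05 counted as called. CPM used TMM-scaled library sizes, and the prior count was 2. Standard errors were the size of the log2 fold change over the square root of F. Counting intervals (95%) and floors (3 counts over the group) cover counting error only. Exact two-sided permutation tests were added for VPS13C and GSTP1. The same test was run on 40948 transcripts, and transcript usage was tested with edgeR's diffSpliceDGE and the Simes method in 9062 genes with at least 2 kept transcripts.

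The comparison, its tests, the first set of alternatives and the gene lists were fixed before the data were examined. Named genes were VPS13C and GSTP1, the 10 genes with the largest rise and the 10 with the largest fall among called genes at least 2-fold changed, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Added to these were up to 4 called members, by smallest p, of each list past the camera threshold or with at least 3 called members, and always of the glutathione transferase, glutathione redox, platinum transport and VPS13 lists. Transcripts named were those of VPS13C and GSTP1 and of the 3 genes with the smallest usage p. Of the called genes, 1131 met the criteria. Other genes are marked as chosen after their values were seen. Of 39 gene lists written, 36 had at least 5 tested members and were tested with camera in limma 3.58.1 with a preset correlation of 0.01, then with an estimated correlation and with fry.

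Alternatives set beforehand were RLE and upper-quartile factors, library size only, DESeq2 1.42.0, limma-voom, no low-count filter (total of at least 1), a filter of 10 CPM in 3 libraries, the replicate number as a block, glmTreat at 1.5-fold, limma on log2(FPKM + 1), and leaving out each library. Chosen after seeing the data were the removal of each library's loess trend (span 0.4) on gene length, the same with GC content, and the length slope as a covariate. Lengths were available for 91.9% and GC content for 98.8% of tested genes. To look for shifts shared by neighbouring genes, 10702 genes with at least 8 CPM were ordered by position and medians taken over 990 windows of 40 genes, every 10 genes. The limit for a window, 0.347 from the overall median, was the 95th percentile of the farthest window median in 1000 shuffles of gene order. Overlapping windows past it were joined into stretches. All tests were repeated on the 10 divisions of the 6 libraries into 3 and 3. Figures were drawn with matplotlib 3.10.9.

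The pipeline was tested on simulated data. Of simulated gene changes it called 17.9% at 1.5-fold, 77.6% at 2-fold and 93.9% at 4-fold, with 8 unchanged genes called among 13717. Only a small part of the simulated genes was changed, while 35.1% of tested genes were called in the real data. Fewer changes make the adjusted threshold stricter, so these shares do not give the sensitivity in the real data. Of transcript changes it called 0% at 2-fold, 5.97% at 4-fold and 16.7% at 16-fold, with 0 unchanged transcripts called. A raised list was called and 0 unchanged lists were. The simulated genes were drawn independently of each other, so this cannot show how often lists of genes that move together are falsely called. For transcript usage, 2.5% of genes were called at 4-fold beside 13 unchanged genes, and 69.5% at 64-fold beside 49 unchanged genes, so usage calls can include false ones. The folds for transcripts and usage were raised after a first version with smaller ones called none.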

Results

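RNA of ME180, an established human cervical epidermoid carcinoma line, was measured by RNA-seq in 6 libraries. In 3 libraries the cells carried an empty vector, and in 3 they carried a single-guide construct against VPS13C, called VPS13C knockout here. VPS13C encodes a bridge-like lipid transfer protein found at contacts between the endoplasmic reticulum and endosomes or lysosomes. Cells of both groups received 2 µM cisplatin, a platinum drug that crosslinks DNA, for 48 h, so each difference below is one between cisplatin-treated populations. Cells without cisplatin were not analysed here. Total counts over genes were 15776546, 15799149 and 15767003 in vector replicates 1 to 3 and 14774065, 15143560 and 15411001 in knockout replicates 1 to 3. The labels do not say whether replicates came from separate cultures or whether the knockout cells were a pool or a clone, so p-values measure the spread between these libraries, which may be technical.

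The first question was whether the targeted gene and GSTP1, the glutathione transferase named in the study's title, differed between the groups. VPS13C (gene 54832, GRCh38 chromosome 15, 61852389 to 62060447) had 48.1, 30.1 and 35.0 CPM (read counts scaled to library size) in the vector libraries and 28.6, 18.6 and 23.7 CPM in the knockout libraries. The means were 37.8 ± 9.30 CPM and 23.7 ± 5.00 CPM (SD, n = 3 each), and every knockout library lay below every vector library. The log2 fold change was −0.67 with a standard error of 0.22, which did not pass the threshold (edgeR quasi-likelihood adjusted p = 0.0513). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The fall of VPS13C passed without vector replicate 2 (−0.81, edgeR quasi-likelihood adjusted p = 0.0378) and without knockout replicate 1 (−0.85, edgeR quasi-likelihood adjusted p = 0.0482). It missed the threshold without vector replicates 1 or 3 (edgeR quasi-likelihood adjusted p = 0.0906 and 0.101). The same held without knockout replicates 2 or 3 (edgeR quasi-likelihood adjusted p = 0.0957 and 0.144). The knockout libraries still held VPS13C RNA, and an RNA level does not show whether the protein was lost.

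GSTP1 (gene 2950, chromosome 11, 67583812 to 67586653), a cytosolic enzyme that conjugates glutathione to electrophiles, was already abundant in the vector libraries. It had 1050, 1638 and 1385 CPM there and 1365, 2320 and 1635 CPM in the knockout libraries. The means were 1358 ± 295 CPM and 1773 ± 492 CPM (SD, n = 3 each), and the groups overlapped. The log2 fold change was 0.39 with a standard error of 0.24 and did not pass the threshold (edgeR quasi-likelihood adjusted p = 0.266 over all genes tested and 0.235 adjusted over the list alone of glutathione transferases). The exact two-sided permutation test gave p = 0.5. GSTP1 lay in a stretch of chromosome 11 whose genes were higher as a group: its 40 nearest measured neighbours, from 66466327 to 68615334, had a median log2 fold change of 0.55, and 32.5% of them lay below GSTP1. The log2 fold change of GSTP1 was 0.22, 0.54 and 0.40 without vector replicates 1 to 3 in turn and 0.53, 0.14 and 0.43 without knockout replicates 1 to 3. Libraries of one group also differed by a trend with gene length. With that trend removed, a setting chosen after seeing the data, the log2 fold change was −0.75 for VPS13C (edgeR quasi-likelihood adjusted p = 4.05e-04) and 0.42 for GSTP1 (edgeR quasi-likelihood adjusted p = 0.00118). Over all alternatives tried the adjusted p ran from 1.48e-11 to 0.652 for VPS13C and from 8.64e-12 to 1 for GSTP1. The low ends came from the length slope as a covariate, also chosen after seeing the data. The high ends came from glmTreat, which tests for a change beyond 1.5-fold. The lowest planned values came from the replicate number as a block, an untested pairing. They were edgeR quasi-likelihood adjusted p = 4.84e-05 for VPS13C and 0.00198 for GSTP1 (log2 fold change 0.37).

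**Figure D1:**
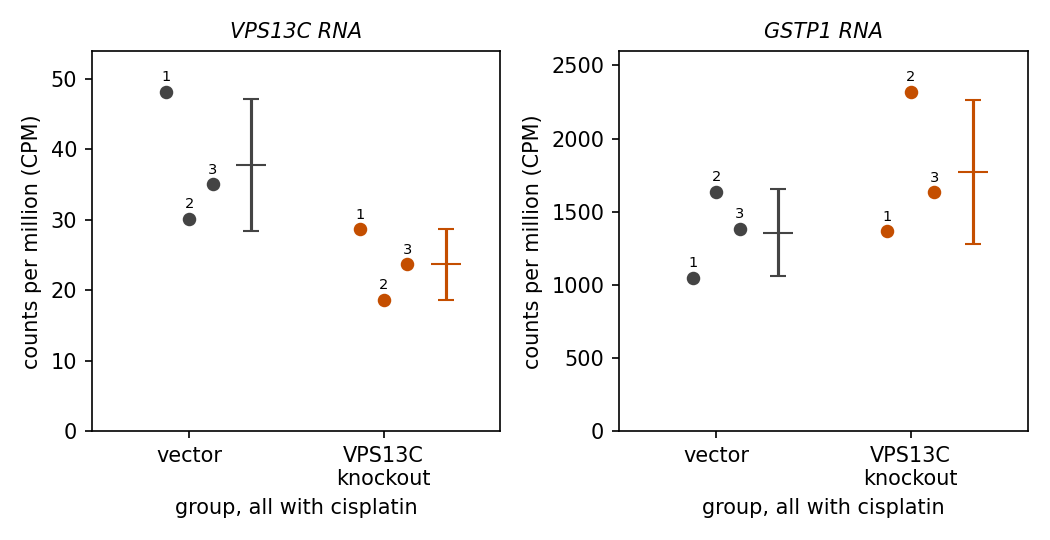
CPM of VPS13C (left) and GSTP1 (right) in each cisplatin-treated library, with the replicate number above each point; the horizontal mark and bars give the group mean ± SD of 3 libraries. VPS13C lies between 18.6 and 28.6 CPM in the knockout libraries and between 30.1 and 48.1 CPM in the vector libraries, and the GSTP1 values of both groups overlap.

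**Figure D2:**
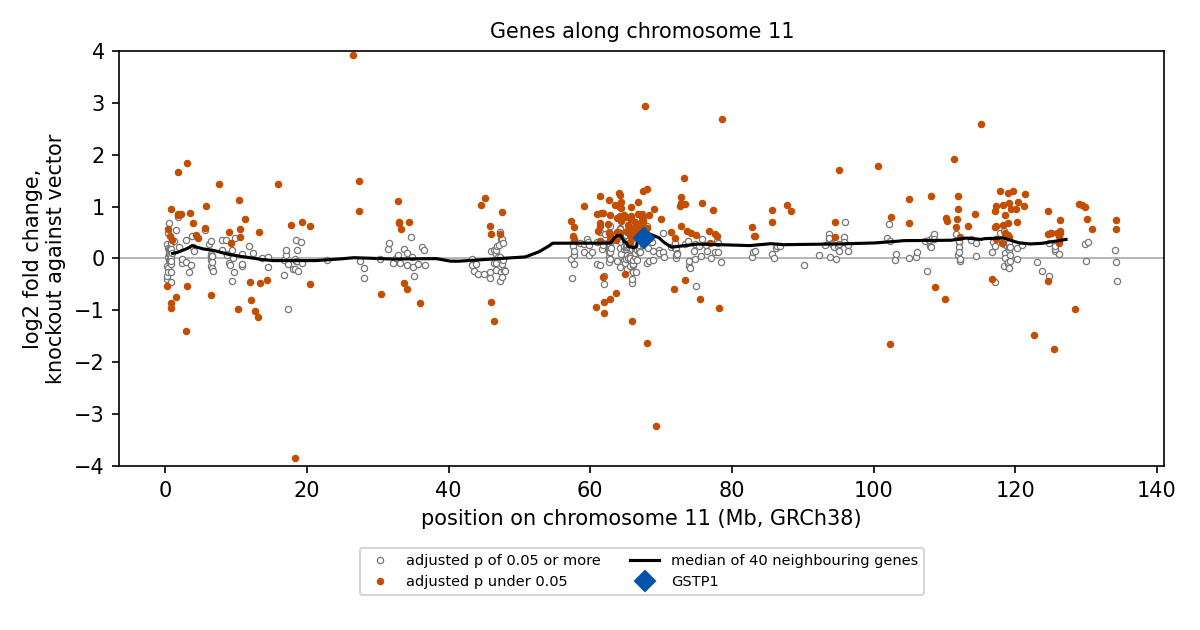
Log2 fold change of 623 measured genes (knockout against vector) by their start on chromosome 11 in Mb; filled points passed the edgeR threshold, the line joins medians of 40 neighbouring genes and the diamond is GSTP1. The line runs near 0 over much of the left part and above 0 on the right, where GSTP1 lies at 0.39; 1 gene lies outside the drawn range of −4 to 4.

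Across all genes the 2 populations differed widely. Of 13717 genes tested, 2440 were higher and 2381 lower in the knockout libraries at an adjusted p under 0.05, and 945 and 783 of these changed at least 2-fold (edgeR quasi-likelihood test). Libraries of the 2 groups did not overlap for 48.5% of tested genes, against 10% by chance. The largest rises were those of SELENBP1, a selenium-binding protein (0.125 ± 0.00520 to 15.1 ± 4.76 CPM, log2 fold change 6.83), and KRT84, a hair keratin (3.28 ± 0.344 to 218 ± 38.4 CPM, 6.05). GPC3, a cell-surface glypican, rose from 2.46 ± 0.0708 to 86.5 ± 12.4 CPM, and ALDH1A1, which oxidises retinaldehyde, from 1.47 ± 0.349 to 42.3 ± 3.84 CPM (SD, n = 3). KRT85, CLEC7A, DYNC1I1, MAT1A, AGR2 and BBOX1 completed the 10 largest rises, with log2 fold changes of 5.06, 5.04, 5.03, 4.75, 4.73 and 4.65.

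Genes that fell farthest included CD200R1, an inhibitory receptor (54.0 ± 8.30 to 0.403 ± 0.135 CPM, log2 fold change −7.04), and the complement component C3 (24.1 ± 0.365 to 0.447 ± 0.165 CPM, −5.73). Genes for the hair keratin-associated proteins KRTAP2-3 and KRTAP3-1 fell from 114 ± 10.6 to 1.81 ± 0.309 CPM and from 1040 ± 126 to 46.2 ± 5.58 CPM (SD, n = 3). ROBO1, an axon guidance receptor, had 535 counts in the vector libraries together and 3 in the knockout libraries, a ratio of 171 with a 95% counting interval of 58.1 to 831. HSD17B2, TNFSF18, ZNF83, VGLL2 and ANKRD1 completed the 10 largest falls, with log2 fold changes of −6.26, −5.38, −4.83, −4.72 and −4.46. The adjusted p of these 20 genes lay between 1.11e-05 and 7.63e-04 (edgeR quasi-likelihood test). ROBO1, CD200R1 and HSD17B2 lay in stretches of chromosomes 3 and 16 whose genes were lower as a group, with medians of −0.46 and −0.50. The total of called genes was 3103 without vector replicate 3 and 3026 without knockout replicate 3.

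Several glutathione transferases were higher in the knockout libraries. Of 15 measured members, GSTP1 included, 8 rose, 0 fell and 7 were not called, both over all genes and adjusted over the list alone, and the median log2 fold change was 0.67. GSTA4, which acts on lipid peroxidation products, rose from 0.876 ± 0.0449 to 8.83 ± 0.488 CPM and GSTA1 from 0.150 ± 0.134 to 2.32 ± 0.753 CPM. GSTM4 rose from 5.62 ± 1.11 to 12.5 ± 1.63 CPM and the microsomal MGST3 from 65.5 ± 9.59 to 123 ± 23.9 CPM (SD, n = 3). All 4 passed the threshold, with adjusted p between 3.00e-05 and 0.00701 (edgeR quasi-likelihood test), and all 4 stayed below GSTP1 in level. The list passed with the preset correlation (camera adjusted p = 0.00978) and not with an estimated one (camera adjusted p = 0.686 with an estimated correlation). It also missed the threshold without vector replicate 1 and with a stricter low-count filter (camera adjusted p = 0.0562 and 0.0564), and over all alternatives its adjusted p ran from 0.00107 to 0.686. Near-identical members of this family, and of the keratin, HLA and histone families below, can share reads, which makes the split between them uncertain.

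Other genes of thiol metabolism and drug transport moved both ways. TXNRD1, the cytosolic thioredoxin reductase, fell from 268 ± 30.6 to 105 ± 10.1 CPM and CHAC2, which degrades glutathione, from 13.1 ± 0.924 to 5.98 ± 0.723 CPM, while OPLAH and PGD rose with log2 fold changes of 1.05 and 0.77. Of 31 genes of glutathione synthesis and thiol redox, 6 rose and 3 fell (camera adjusted p = 0.990; 6 and 3 adjusted over the list alone). The median was −0.08 and the mean 0.02, of opposite sign. Among 30 NRF2 target genes 9 rose and 7 fell (camera adjusted p = 0.507; 11 and 7 adjusted over the list alone), with AKR1B10 and PIR up at 3.30 and 1.88, the latter in a stretch of chromosome X with a median of 0.43. Of 21 genes of platinum uptake, efflux and copper transport, 6 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.648). The organic cation exporter SLC47A2 rose from 10.3 ± 1.69 to 46.1 ± 5.37 CPM and the efflux pump ABCC1 from 114 ± 6.50 to 184 ± 10.6 CPM. ABCC3 fell from 61.7 ± 2.09 to 18.2 ± 1.53 CPM and SLC47A1 from 7.12 ± 0.978 to 3.35 ± 0.114 CPM (SD, n = 3). The copper transporter SLC31A1, chosen after its values were seen as a known route of platinum uptake, had a log2 fold change of 0.11 with a standard error of 0.13. Of 4 measured metallothionein genes 1 rose and 1 fell, too few for a list test; these were MT1F (log2 fold change 1.45) and MT2A (320.3 to 160.2 CPM), named after their values were seen.

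Within the VPS13 family and related lipid transfer proteins, VPS13B and VPS13D rose with log2 fold changes of 0.77 and 0.62, and ATG2A fell by 0.29 on the log2 scale. These 3 calls among 10 members had edgeR quasi-likelihood adjusted p values of 0.0323, 0.0375 and 0.0420. Each of the 3 calls was lost without vector replicate 2, vector replicate 3, knockout replicate 1 or knockout replicate 3 (edgeR quasi-likelihood adjusted p from 0.0804 to 0.144), and that of ATG2A also without vector replicate 1 or knockout replicate 2 (edgeR quasi-likelihood adjusted p = 0.0522 and 0.0735). ATG2A lay in a stretch of chromosome 11 with a median of 0.35. Adjusted over the list alone, 2 rose and 2 fell, VPS13C among the latter (adjusted p = 0.0456 from the edgeR quasi-likelihood p-values). The list did not pass (camera adjusted p = 0.772).

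Many genes of the squamous epithelium were higher in the knockout libraries. Of 38 measured genes of keratinocyte differentiation and the cornified envelope, 23 rose and 3 fell (25 and 4 adjusted over the list alone), with a median log2 fold change of 0.93. KRT1 and KRT10, the keratin pair of suprabasal epidermis, rose with log2 fold changes of 4.09 and 1.81. The desmosomal cadherin DSG1 rose from 2.91 ± 0.460 to 29.6 ± 5.16 CPM and the envelope precursor IVL from 39.7 ± 3.24 to 146 ± 13.0 CPM (SD, n = 3). The members that fell were KLK5, KLK7 and KRT80, named after their values were seen; KLK5 and KLK7 are proteases of the outer epidermis. Of 24 genes of basal squamous epithelium, 13 rose and 2 fell, with the same counts adjusted over the list alone and a median of 0.61. SOX2, a transcription factor, rose from 4.14 ± 0.620 to 36.2 ± 2.36 CPM, and KRT6C, KRT6B and COL7A1 rose with log2 fold changes of 2.73, 1.86 and 1.09. CDH3, named after its values were seen, was among the members that fell. SOX2 lay in a stretch of chromosome 3 with a median of −0.45. KRT1, KRT6B, KRT6C and KRT7, like KRT84 and KRT85, lay in a stretch of chromosome 12 that holds many keratin genes and had a median of 0.35, and 6 of the 15 called basal genes lay in stretches shifted their way. List members with at least 8 CPM were among the genes that defined the stretches. With basal list members left out, the neighbours of the basal genes had a median of −0.053. The 2 lists had camera adjusted p = 4.11e-06 and 0.00247 in that order, but adjusted p = 0.540 and 0.207 with an estimated correlation. Of 17 genes of simple and glandular epithelium, 2 rose and 6 fell, and the list did not pass (camera adjusted p = 0.10; the same counts adjusted over the list alone). It passed without knockout replicate 2, with the replicate number as a block and with length and GC trends removed (camera adjusted p = 0.0293, 0.0349 and 0.0434), and over all alternatives its adjusted p ran from 0.0293 to 0.717. KRT7 fell from 23.6 ± 4.56 to 3.19 ± 1.30 CPM and KRT20 from 3.92 ± 0.376 to 0.338 ± 0.126 CPM, while EPCAM fell from 171 ± 7.23 to 103 ± 5.47 CPM and AGR2 rose.

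Inflammatory genes that NF-kB controls were lower. Of 24 measured members 0 rose and 18 fell (0 and 19 adjusted over the list alone), with a median log2 fold change of −1.57. IL1B fell from 35.5 ± 2.68 to 7.16 ± 0.111 CPM, the chemokine CCL20 from 14.2 ± 0.541 to 1.74 ± 0.324 CPM, IL36G from 73.1 ± 3.40 to 20.4 ± 1.73 CPM and LIF from 22.9 ± 1.67 to 5.00 ± 0.925 CPM (SD, n = 3). Their adjusted p lay between 3.04e-05 and 1.30e-04 (edgeR quasi-likelihood test). Immediate early and AP-1 genes were lower too: of 33 members 2 rose and 25 fell, with the same counts adjusted over the list alone and a median of −0.95. The MAP kinase phosphatases DUSP4, DUSP5 and DUSP1 fell with log2 fold changes of −3.34, −2.79 and −2.14, and ETV5, a transcription factor induced by ERK signalling, with −3.86. ETV5 lay in a stretch of chromosome 3 with a median of −0.45. The 2 risers were KLF4 and EGR3, named after their values were seen, and EGR1, named likewise, had means of 450 and 448 CPM. The lists passed with the preset correlation (camera adjusted p = 2.69e-09 and 3.79e-09) and not with an estimated one (adjusted p = 0.0701 and 0.368 with an estimated correlation).

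Genes of the ATF4 response and p53 targets were lower as well. Of 32 genes of the ATF4 integrated stress response, 3 rose and 13 fell (3 and 16 adjusted over the list alone; median −0.34), and of 33 p53 target genes 4 rose and 12 fell, also when adjusted over the list alone (median −0.24). GDF15, a secreted stress cytokine on both lists, fell from 519 ± 30.7 to 51.6 ± 3.78 CPM. PPP1R15A, which restores translation after stress, fell from 444 ± 38.1 to 165 ± 7.42 CPM, and ATF3 from 83.8 ± 4.42 to 38.2 ± 1.14 CPM, while VLDLR rose from 21.1 ± 0.907 to 49.7 ± 2.75 CPM. GADD45A fell from 194 ± 9.41 to 87.6 ± 3.56 CPM (SD, n = 3), and AEN and ZMAT3 fell with log2 fold changes of −0.70 and −0.84. CDKN1A, the p21 gene and a central p53 target chosen after its values were seen, had a log2 fold change of −0.17 with a standard error of 0.11. The p53 targets that rose were CCNG1, SPATA18, CMBL and XPC, named after their values were seen. GDF15 lay in a stretch of chromosome 19 with a median of −0.47, and VLDLR in one of chromosome 9 with a median of 0.40. The ATF4 and p53 lists had camera adjusted p = 1.47e-04 and 0.0119, and adjusted p = 0.263 each with an estimated correlation.

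Interferon-stimulated genes were higher, though not all of them. Of 41 members, counted with genes of the cGAS-STING pathway, 19 rose and 4 fell (21 and 4 adjusted over the list alone), with a median of 0.40. HERC6 rose from 20.7 ± 1.13 to 59.8 ± 2.92 CPM, MX1 from 17.6 ± 2.22 to 45.8 ± 0.534 CPM, OAS2 from 24.8 ± 0.830 to 55.4 ± 0.528 CPM and IRF9 from 27.0 ± 0.959 to 61.0 ± 3.65 CPM (SD, n = 3), the last in a stretch of chromosome 14 with a median of 0.34. The 4 that fell were CGAS, which senses cytosolic DNA, IFITM2, PARP14 and IFIT2, named after their values were seen. ISG15, chosen in the same way, had a log2 fold change of 0.07 with a standard error of 0.25. Of 16 genes of MHC class I antigen presentation 4 rose and 0 fell (2 and 0 adjusted over the list alone; median 0.25), among them B2M at 0.63 and HLA-F at 0.89. Camera adjusted p was 1.47e-04 and 0.0373 for the 2 lists, and adjusted p was 0.128 and 0.589 with an estimated correlation. The MHC list missed the threshold without vector replicate 1 or knockout replicate 2 (camera adjusted p = 0.0899 and 0.0855), and its adjusted p ran from 0.00695 to 0.589 over all alternatives.

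DNA replication genes were slightly lower as a list, and the list of mitotic genes did not pass the threshold. Of 41 genes of G1/S and DNA replication, 1 rose and 11 fell (1 and 8 adjusted over the list alone; median −0.19), and 6 of these 12 lay in chromosome stretches shifted the same way. CDC6, which loads the replicative helicase, fell from 187 ± 3.51 to 115 ± 6.59 CPM (SD, n = 3). The helicase subunit MCM2 fell by 0.65 on the log2 scale and lay in a chromosome 3 stretch with a median of −0.37. The riser was POLA1 (0.61), named after its values were seen. Of 11 replication-dependent histone genes 0 rose and 5 fell, also when adjusted over the list alone (median −0.54), with H2BC12 and H2BC21 at −0.97 and −0.78. Of 43 genes of G2/M and mitosis, 5 rose and 2 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.513). KIF20A and CDC25C rose by 0.95 and 0.72 on the log2 scale, and both lay in a chromosome 5 stretch with a median of 0.35. The replication and histone lists had camera adjusted p = 0.00686 and 0.0491, and adjusted p = 0.263 and 0.540 with an estimated correlation. The histone list missed the threshold without vector replicate 1, without knockout replicate 1, with another size factor and with the length trend removed (camera adjusted p = 0.0738, 0.0894, 0.0519 and 0.0605), and over all alternatives its adjusted p ran from 0.00603 to 0.540.

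The lists of cholesterol synthesis and of the respiratory chain passed as higher by small amounts (camera adjusted p = 0.0315 and 0.00280), although few respiratory members were called. Neither passed with an estimated correlation (adjusted p = 0.263 and 0.789 with an estimated correlation). Of 25 genes of cholesterol synthesis and uptake 7 rose and 1 fell (6 and 1 adjusted over the list alone; median 0.23). The sterol desaturase SC5D rose from 56.8 ± 4.50 to 115 ± 10.8 CPM and SREBF2, the regulator of the pathway, from 118 ± 5.46 to 191 ± 5.07 CPM (SD, n = 3). STARD4 rose with a log2 fold change of 1.57, and SC5D and STARD4 lay in stretches of chromosomes 11 and 5 with medians of 0.37 and 0.35. Of 47 nuclear-encoded subunits of oxidative phosphorylation 5 rose and 0 fell (1 and 0 adjusted over the list alone; median 0.33). Without vector replicate 1 both missed the threshold (camera adjusted p = 0.0641 and 0.0642), as did the sterol list with a stricter low-count filter (0.0504) and the respiratory list without knockout replicate 2 (0.0717) and with fry (adjusted p = 0.311). Over all alternatives adjusted p ran from 0.00141 to 0.263 and from 1.16e-06 to 0.789.

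**Figure D3:**
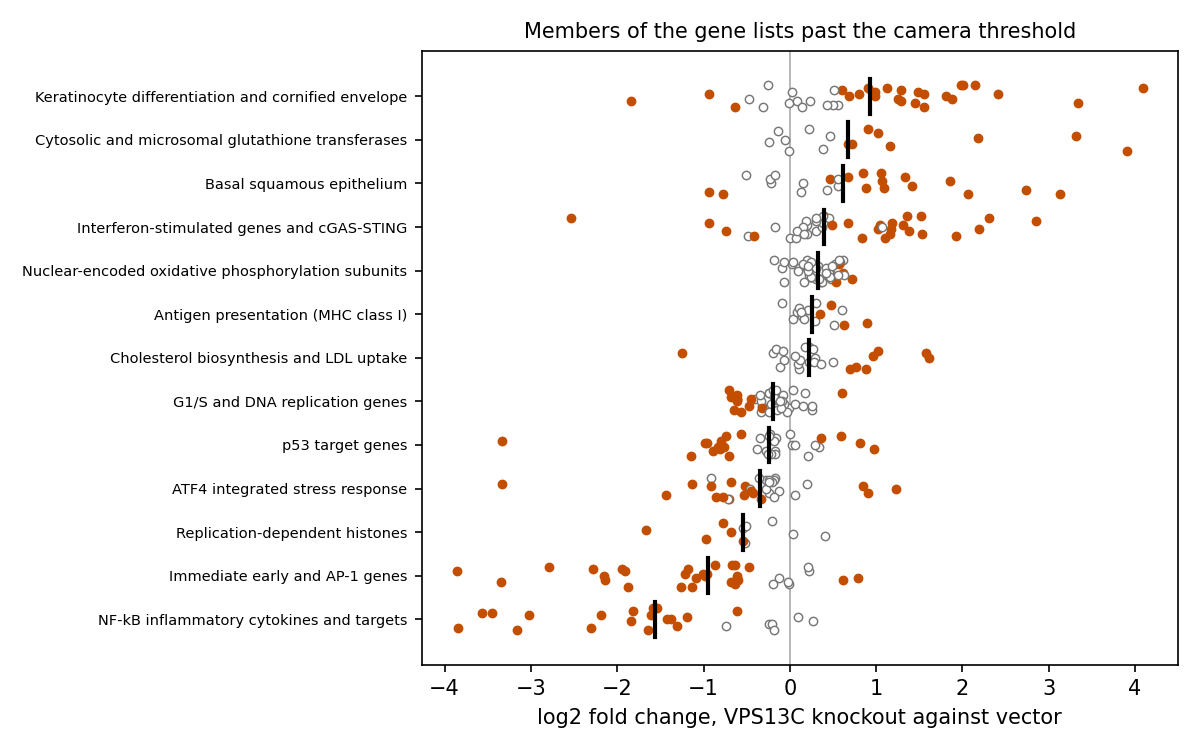
Log2 fold change (knockout against vector) of each measured member of the 13 gene lists that passed the camera threshold with the preset correlation, 1 row per list; filled points passed the edgeR threshold, and the vertical bar is the list's median. Medians run from −1.57 for NF-kB genes to 0.93 for keratinocyte differentiation.

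In all, 13 of 36 lists tested with camera passed the threshold, 7 higher and 6 lower. With an estimated correlation 0 passed, and the lowest camera adjusted p was 0.0701. Among the 13 lists, NF-kB, basal squamous, cholesterol and interferon genes had estimated correlations of −0.013, −0.036, −0.005 and 0. These lie at or below the preset 0.01, so a higher correlation does not account for their loss. For NF-kB genes the unadjusted camera p was 7.48e-11 with the preset and 0.00195 with the estimate. In these lists the loss came from how each form of the test judges significance, not from more correlated members. The rest of the 13 had estimates above the preset, up to 0.685 for the respiratory list. Without vector replicate 1 the preset test passed 8 lists. Each other division of the 6 libraries into 3 and 3 put 7 to 12 lists past it, while calling 0 genes.

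Single transcripts were measured with far more spread than genes. Of 40948 transcripts tested, 478 were higher and 443 lower in the knockout libraries (edgeR quasi-likelihood test). The GSTP1 transcript NM_000852.4 had a log2 fold change of 0.38 (edgeR quasi-likelihood adjusted p = 0.691). The VPS13C transcripts NM_017684.5 and NM_018080.3 had −0.61 and −1.43 (edgeR quasi-likelihood adjusted p = 0.325 and 0.546). The test of the balance between transcripts of one gene called 21 of 9062 genes, among them SEC31A and GGA2. On simulated data this test also called 13 to 49 unchanged genes, and it called 6 genes with the replicate number as a block and 3 with a stricter low-count filter. SEC31A, a coat protein of vesicles leaving the endoplasmic reticulum, had 0 counts of NM_001077207.4 in the vector libraries and 1118 in the knockout libraries, at least 389-fold higher against a floor of 3 counts over the group. GGA2, a sorting adaptor of the Golgi, had 423 counts of XM_024450200.1 in the vector libraries and 0 in the knockout libraries, at least 135-fold lower against the same floor, but this transcript missed the threshold (edgeR quasi-likelihood adjusted p = 0.0520). Transcripts of one gene share most reads, and leaving out vector replicates 1 to 3 in turn left 294, 27 and 17 called transcripts and leaving out knockout replicates 1 to 3 left 50, 164 and 19. The count of genes called for this balance was 13, 6 and 13 without vector replicate 2, vector replicate 3 and knockout replicate 1, and 2 other divisions of the 6 libraries gave 29 and 196.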

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

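The settings that remove trends on gene length or GC content were chosen only after the data were seen; the others were planned. The alternative of another pseudocount was not run, since the files hold counts. Among called genes, named genes and gene lists 0 calls reversed under the settings run for them; for transcripts and usage only counts were compared. The 4821 called genes became 7939 with the replicate block (4049 higher, 3890 lower), 1561 with glmTreat at 1.5-fold (858 higher, 703 lower), 9634 with the length slope as a covariate (4855 higher, 4779 lower) and 7681 with length and GC trends removed (3868 higher, 3813 lower). Leaving out 1 library gave 3026 to 5043 genes (1551 to 2552 higher, 1475 to 2491 lower), with 3103 without vector replicate 3 and 3026 without knockout replicate 3. Of 150 other named genes DESeq2, limma-voom and the block kept all 150 calls, glmTreat 99, and the single omissions 128 to 144. With library size only 46.5% of calls were higher, against 50.6%. The numbers may not pair the libraries: deviations of equal numbers correlated across genes at 0.65, 0.68 and −0.22, and 4 of 6 libraries were closest to their own number. The signs followed the gene length trend. Its rho in vector and knockout libraries was 0.602 and 0.642 for number 1, −0.59 and −0.614 for number 2, and −0.412 and 0.325 for number 3. Blocked values such as 7939 thus rest on an untested pairing.

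The log2 fold change of VPS13C passed with RLE factors (−0.6812), DESeq2 (−0.6815), no filter (−0.6718), the block (−0.6687), the length trend removed (−0.7495), the length slope (−0.7788) and length and GC trends removed (−0.7234), and ran from −0.8464 to −0.4646 without 1 library. That of GSTP1 passed with the block (0.3736), the length trend removed (0.4159), the length slope (0.4866) and length and GC trends removed (0.4131). Against 13 lists, 0 passed with an estimated inter-gene correlation, 21 with fry, and 8 to 14 without 1 library. The 921 called transcripts became 226 with the block (137 higher, 89 lower), the lower ones 277 without a filter, and 17 to 294 without 1 library (8 to 170 higher, 9 to 124 lower). Genes with changed transcript usage numbered 3 with a stricter filter, 93 with a gene-level F-test, 6 with the block and 6 to 19 without 1 library. Apart from the trend removals, the slope and fewer samples, the cause was not tested.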

Other observations

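Tests of the order of genes, both tests of GSTP1 and the divisions of the libraries for called genes were chosen only after the result was seen. Members of several other lists moved both ways between the groups. Of 23 mesenchymal genes 4 rose and 12 fell (camera adjusted p = 0.319; 5 and 12 adjusted over the list alone). COL5A1, a fibrillar collagen, rose from 2.49 ± 0.374 to 16.2 ± 0.149 CPM and TGFBI from 117 ± 3.01 to 438 ± 15.7 CPM, (SD, n = 3), while the receptor AXL fell with a log2 fold change of −1.87. Of 22 TGF-beta and YAP target genes 4 rose and 10 fell (camera adjusted p = 0.0866; 5 and 10 adjusted over the list alone), ANKRD1 among the latter, and the list passed without vector replicate 2 and with the replicate block (camera adjusted p = 0.0411 and 0.0469), with a range of 0.0155 to 0.686 over all alternatives. Of 22 Wnt and Notch targets 5 rose and 4 fell (camera adjusted p = 0.714; the same adjusted over the list alone; median 0.15 and mean −0.01), with DKK1, a Wnt inhibitor, down from 337 ± 24.0 to 74.7 ± 5.16 CPM and NOTCH3 up by 1.28 on the log2 scale. Of 34 hypoxia and glycolysis genes 9 rose and 7 fell (camera adjusted p = 0.513; the same adjusted over the list alone), with the glucose transporter SLC2A1 at 1.39 and the lactate exporter SLC16A3 at −1.47. Of 26 genes of fatty acid synthesis and lipid droplets 8 rose and 3 fell (camera adjusted p = 0.513; 9 and 4 adjusted over the list alone; median −0.08 and mean 0.16), with the desaturase SCD at 1.36 and SREBF1 at 1.17.

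The lysosome and autophagy lists, chosen for where VPS13C protein sits, did not pass with camera. Of 50 lysosomal genes 8 rose and 6 fell (camera adjusted p = 0.335; the same adjusted over the list alone), with the cathepsin CTSC at 0.92 and PSAP at −0.73. Of 42 autophagy genes 10 rose and 6 fell (camera adjusted p = 0.513; 10 and 7 adjusted over the list alone), with MAP1LC3B at −0.80 and SQSTM1 at −0.87, and 7 of these 16 lay in stretches shifted their way. Of 32 apoptosis genes 5 rose and 7 fell (camera adjusted p = 0.654; 5 and 8 adjusted over the list alone), and BMF, a BH3-only protein, rose from 2.73 ± 0.485 to 38.2 ± 3.85 CPM. For DNA repair, 5 of 26 excision repair genes rose and 3 fell (camera adjusted p = 0.990; median 0.02 and mean −0.05), with ERCC2 at −1.03, and 1 of 35 Fanconi and recombination genes rose and 6 fell (camera adjusted p = 0.513; 1 and 4 adjusted over the list alone). The unfolded protein response (2 rose and 4 fell of 25; camera adjusted p = 0.648), heat shock proteins (1 and 5 of 21; 0.10) and cytosolic ribosomal proteins (0 and 1 of 52; 0.639) did not pass with camera over all libraries, but the ribosomal list did without knockout replicate 2 (camera adjusted p = 0.0205, with a range of 0.0205 to 0.966 over all alternatives). The ribosomal gene that fell was RPL24 (−1.36), named after its values were seen. Among markers of other cells, 2 of 5 fibroblast markers rose and 1 fell (camera adjusted p = 0.513), 1 and 3 of 5 endothelial markers (0.256), 1 and 2 of 5 neural and melanocytic markers (0.748), 2 and 2 of 8 genes that mark other lines (0.513) and 0 and 2 of 4 immune markers. Counts were the same adjusted over the list alone for excision repair and for each of these lists, with highest mean levels of 365, 20.7, 54.2, 31.7 and 60.9 CPM for FBLN1, EGFL7, MBP, ESR1 and CD68. FLT1 had 66 and 2 counts, a ratio of 31.6 (95% counting interval 8.41 to 266). Mitochondrially encoded genes had 0 members in the gene table. With fry, which asks whether a list moves on balance one way and does not compare it with other genes, 9 lists that missed with camera passed: autophagy (adjusted p = 0.0235), fatty acid synthesis (4.83e-04) and hypoxia (0.0279) as higher, heat shock (4.83e-04) and TGF-beta and YAP targets (0.0155) as lower, and the fibroblast, endothelial, neural and other-line lists (2.36e-04, 0.00708, 0.00625 and 4.83e-04).

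Neighbouring genes shifted together in 108 of 990 windows, 45 higher and 63 lower, in 20 stretches that held 16.1% of ordered genes and 24.4% of called ones. The stretches spanned 2.5 to 71 Mb. The largest were a lower one of 310 genes over 62.6 Mb of chromosome 16 and a higher one of 170 genes over 71 Mb of chromosome X. The higher one that holds GSTP1 had 70 genes over 6.1 Mb. Chance order is argued against, since 0 of 1000 shuffles reached the farthest median of −0.85, and so are GC and length trends, since 94.4% of the windows stayed past the limit with both removed. A difference in DNA copy number between the 2 cell populations was looked at across 99 ribosomal protein and oxidative phosphorylation genes. Their log2 fold change followed the neighbours' median (Spearman rho 0.384, permutation p = 0.00018, Pearson r 0.534, and 0.40 without the 2 farthest genes). Genes are not independent replicates, and rho over all 10702 ordered genes was 0.303. Any shift shared by neighbours would give such a rho, so copy number is a candidate that this test cannot tell from other regional causes. Of the 99 genes, the 8 in higher stretches had a median of 0.50, but the 5 in lower stretches one of −0.07. No DNA was measured, and separate growth of the populations, the construct's action and clonal selection were not tested.

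GSTP1 may share such a shift, since 32.5% of its 40 nearest neighbours lay below it and their median was 0.55. The length trend is argued against as the whole cause, since the log2 fold change was 0.416 with it removed. An effect of VPS13C loss on GSTP1 itself stays open and was not tested apart from its neighbourhood.

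The keratinocyte and basal squamous lists were higher and the NF-kB and immediate early lists lower. With the gene length trend removed 4 of the 4 lists passed in the same direction. As a check on a shift shared with chromosomal neighbourhoods, neighbours were subtracted, and 4 of the 4 medians kept over 50% of their size. The neighbours' own medians were −0.033, −0.053, −0.036 and −0.048 for the lists in the order above. The NF-kB and immediate early lists had medians of −1.57 and −0.95, and the lowest stretch median was −0.50. For these lists the outcome was therefore likely from the start. A difference in squamous differentiation between the populations is a hypothesis that these tests leave open, whether it came with VPS13C loss or with the separate history of the cells. With an estimated correlation 0 lists passed.

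The 10 divisions of the 6 libraries into 3 and 3 are too few for a share under 0.05. All but the real one also put libraries of both groups on each side. A group difference then widens the spread within sides, so low counts there were likely from the start. As many called genes came from 1 of the 10 divisions, the real one, with 4821 genes and 0 as the highest of the others. As many called transcripts came from 1, with 921 and 0. As many lists came from 1, with 13 in the real division and 7 to 12 in the others. As many genes with changed transcript usage came from 3, with 21 in the real division and 196 in the highest other, vector replicate 1 with knockout replicates 1 and 3, which points to a structure of the libraries: these 3 were the ones whose deviations correlated positively with gene length across genes (rho 0.602, 0.642 and 0.325).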
